A study of Saccharomyces cerevisiae and Neurospora crassa and Schizosaccharomyces pombe with 13 samples.

How the data were processed

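The series describes 13 libraries of nucleosome footprints made by MNase-seq, in which micrococcal nuclease digests the DNA between nucleosomes and the protected fragments are sequenced. Per the labels' protocols, formaldehyde at 1% fixed the cells, over 15 min in the yeasts and 10 min in Neurospora crassa, and they were then spheroplasted and digested. In the standard protocol the crosslinks were reversed overnight, the DNA was extracted with phenol and chloroform, and the mononucleosome band was cut from a gel. In the rapid protocol RNase treatment took 30 min, reversal at 65 degrees took 45 min, and the DNA was recovered on a column and dephosphorylated for 10 min, and the labels' protocols mention no gel step for it. Per the submitters' processing notes, CASAVA and Bowtie2 were used on the reads, and the builds named there are sacCer3, R64 and ASM294v2.

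The deposited file analysed here is a gene annotation of N. crassa in GTF format and belongs to no library. It holds 81022 records of 4 kinds, namely 30794 exon, 28632 CDS, 10811 start codon and 10785 stop codon records. The score field is empty in all of them (0 records with a score), so the file carries no read number, coverage or other measurement of a library. The values used are the first and last base of each record, counted from 1 in bp along the sequence. The file has no header; its source field names the NC12 gene calls, and its file name adds strain OR74A and the word "fixed". What was corrected, and with which tool, is not given in the sources used here. The 7 sequences carry the numbers 1 to 7 in their names and are referred to by them. Footprint coverage, read depth, fragment lengths and nucleosome positions of the 13 libraries were not analysed here, so no comparison between libraries, protocols, strains or growth conditions was tested.

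The records were read into transcripts and genes by their identifiers. There were 0 duplicate records. Every gene had a CDS, and the coding length of all 10785 transcripts was a multiple of 3 (the stop codon is not part of the CDS records). A gene's span ran from the first to the last base of any of its transcripts. Counts of exons, introns and UTR bases used the longest transcript of each gene by exonic length. Neighbours were consecutive genes ordered by start. A pair was called divergent where the 2 starts face each other, convergent where the 2 ends do, and tandem otherwise. The gap was the number of bases between the 2 spans, below 0 where they overlap. A start was called clear where no other gene overlapped the 1000 bp before it.

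An annotation has no biological replicates. The 7 sequences, each with more than 100 genes, were therefore used as the units: a quantity was computed on each, and is given as the mean ± SD over sequences. The SD describes differences between sequences and not an error of measurement. Differences were tested with an exact two-sided sign-flip permutation test over the 7 sequences, whose smallest possible p is 0.0156. Genes were not treated as replicates in it. The test of the surroundings of the longest gene-free intervals shuffled single gaps within each sequence instead. There were 2 planned tests, adjusted together by the Benjamini-Hochberg method. The results, tests and most alternatives were fixed before the data were examined; the longest gene-free intervals, the comparison of species, the tests of explanations and hypotheses in the closing section that were not planned as alternatives, and 3 further alternatives were added after.

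The genes named in the text follow a rule fixed at the same time: the gene with the longest span, that with most exons, that with most transcripts, that with the longest intron, and the divergent pair with the longest gap. Lists of histone, clock and light response, carotenoid, DNA methylation and heterochromatin genes had also been set, to be matched by symbol. The annotation pairs its identifiers with no symbols, and 0 of its 9730 gene identifiers matched the table of symbols used here, which covers Saccharomyces cerevisiae; those lists were not used. No N. crassa genome sequence was used, so base composition and splice sites were not examined. Coordinates are those of the annotation. For the comparison of species, coding spans of protein-coding genes were taken from R64 for S. cerevisiae and from ASM294v3 for Schizosaccharomyces pombe. The latter is a different version from the ASM294v2 of the processing notes, so only distances, and no coordinates, are given for S. pombe.

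The calculations were run in Python 3.11.15 with NumPy 2.4.6, and figures were drawn with matplotlib 3.10.9. They were tested on a simulated annotation of 7000 genes on 7 sequences. No simulated neighbours overlapped, and no gene had several transcripts or a UTR after its coding region. The gap calculation was therefore not tested on overlapping pairs. A simulated difference of 600 bp between divergent and convergent gaps was recovered as 573.5 bp, and a simulated difference of 10 bp between first and later introns as 9.86 bp. With no difference simulated the values were -20.9 bp and -0.50 bp. The simulated share of genes with a 5' UTR, 71.0%, was recovered exactly. The sign-flip test called 3.75% of 400 sets drawn with no difference, at a threshold of 0.05.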

Results

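The study prepared nucleosome footprints from 3 fungi with 13 MNase-seq libraries in 8 groups. Budding yeast, S. cerevisiae of the W303 background, gave 10 libraries. These cover wild-type cells and isw2 mutants, with 2 libraries each for the standard protocol in liquid culture, 1 each for the rapid protocol in liquid culture and 2 each for the rapid protocol on cells taken from patches on agar. The fission yeast S. pombe gave 1 library and the filamentous fungus N. crassa gave 2, all with the rapid protocol. The N. crassa libraries came from conidia, its asexual spores, grown for 3.5 h until over 70% had germinated. In total 4 libraries used the standard protocol and 9 the rapid one. The design sets the rapid protocol against the standard one, the mutant against the wild type, patches against liquid culture and the species against each other. Footprints and sequencing depth of these libraries were not analysed here, and no such comparison is reported.

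The gene disrupted in the mutant, ISW2 (YOR304W), encodes the catalytic subunit of an ATP-dependent remodeler that slides nucleosomes. The labels give a KANMX or a URA3 marker in its place, and both markers occur among the standard and among the patch libraries. In R64 its coding sequence occupies chromosome XV, positions 884514 to 887876 on the plus strand, 3363 bp. It lies 379 bp after CPA1, on the same strand, and 643 bp before BIL1, which is on the opposite strand and converges on it. Its footprint profile was not analysed here, so the loss of the gene could not be checked in the libraries.

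The deposited annotation gives the gene starts on which N. crassa footprints can be aligned. It holds 9730 genes and 10785 transcripts on 7 sequences, with 4898 genes on the plus and 4832 on the minus strand. The median gene span was 2129 bp (quartiles 1454 and 3041 bp), and the median coding length was 1260 bp. Spans reached 1000 bp or more in 88.6% of genes. Most genes, 8832, had 1 transcript. Of the 898 genes with several, 506 (56.3%) had transcripts that began at different bases, and the outermost starts of these lay a median of 195.5 bp apart (quartiles 84 and 435 bp). Sequence 1 carried the most genes, 2347, and sequence 6 the fewest, 988.

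Whether a start marks a transcript or merely a coding region depends on the UTRs, the transcribed ends outside the coding region. A 5' UTR of at least 1 bp was annotated for 7657 genes, or 78.0% ± 2.68 (SD over the 7 sequences), and a 3' UTR for 7789 genes, or 79.5% ± 2.47. The remaining 2073 genes without a 5' UTR began at their start codon, and 1646 genes (16.9%) had neither UTR. Annotated 5' UTRs had a median length of 320 bp (quartiles 178 and 547 bp) and 3' UTRs of 350 bp (quartiles 216 and 553 bp). Of the annotated 5' UTRs, 80.9% were 150 bp or longer in exonic bases, about the length of DNA wrapped in a nucleosome core or more. Introns are not counted in this length, so the stretch of DNA is longer where an intron lies within the 5' UTR. An intron interrupted the 5' UTR in 1012 genes, 13.2% of those that had one. Transcript starts and ends were not tested against any transcript data here.

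The gap between neighbouring genes was compared by orientation. Divergent and tandem gaps lie before starts and set how much of an average profile there is free of other genes. Convergent gaps hold no start. Neighbours whose ends face each other lay much closer than neighbours whose starts do. The 2680 convergent pairs had a median gap of 172 bp, the 2682 divergent pairs 761 bp and the 4361 tandem pairs 827 bp. Averaged over sequences, the medians were 181 ± 51.6 bp for convergent, 776 ± 85.9 bp for divergent and 831 ± 62.4 bp for tandem pairs (SD, n = 7 sequences). The divergent median exceeded the convergent one on 7 of 7 sequences, by 595 ± 73.3 bp (SD), which passed the exact two-sided sign-flip permutation test (p = 0.0156, adjusted p = 0.0156, the smallest that 7 sequences allow).

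**Figure D1:**
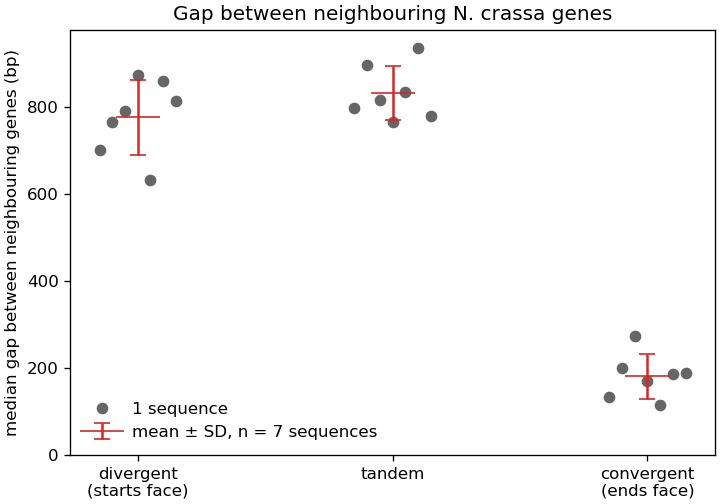
Median gap in bp between neighbouring N. crassa genes, by orientation of the pair. Each grey point is 1 of the 7 sequences and the red marks give the mean ± SD; convergent medians lie between 115 and 274 bp, below every divergent (632 to 871.5 bp) and tandem (765.5 to 935 bp) median.

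The annotated spans of convergent genes often overlapped. Spans overlapped in 966 convergent pairs, 35.4% ± 2.62 of those on a sequence, in 116 divergent pairs, 4.24% ± 1.07, and in 48 tandem pairs, 1.01% ± 0.452. Between coding spans, the overlaps came to 0 of the 2684 convergent pairs and 3 of the 2686 divergent ones, so each convergent overlap involved a UTR. Gaps under 150 bp, overlaps included, made up 47.9% ± 2.69 of convergent, 8.20% ± 1.06 of divergent and 8.53% ± 1.28 of tandem pairs. With gaps measured between coding spans, the divergent pairs still exceeded the convergent ones by 608 ± 121 bp, on 7 of 7 sequences (exact permutation p = 0.0156). Leaving out overlapping pairs selects them by the gap itself and removes 966 convergent but 116 divergent pairs, which narrows the difference by construction, to 190 ± 128 bp (6 of 7 sequences above 0, exact permutation p = 0.0313). With means in place of medians it was 943 ± 775 bp, also on 6 of 7. Means are open to single long gaps, such as a divergent one of 321175 bp on sequence 5 and a convergent one of 347790 bp on sequence 7.

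Starts with another gene close upstream outnumbered clear ones. No other gene overlapped the 1000 bp before the start in 4123 of 9730 genes, or 42.7% ± 2.03 (SD, n = 7 sequences). For 283 genes, 2.79% ± 0.601, the start itself lay within another gene. Counting same-strand neighbours alone, 73.5% of starts were clear. Measured from coding spans the share was 70.9%, and over a window of 200 bp it was 87.0%.

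Introns were short and present in most genes. Of the 9730 genes, 7941 (81.6%) had at least 1 intron, 1789 (18.4%) had a single exon, 3321 had 2 exons and 519 had 6 or more. The 16983 introns of the longest transcripts had a median length of 75 bp (quartiles 62 and 112 bp) and ranged from 21 to 1884 bp. The mean of the sequence medians was 75.3 ± 0.756 bp, and 83.4% of introns were under 150 bp. By place, the 1154 introns of 5' UTRs had a median of 101 bp, the 15528 within coding spans 74 bp and the 301 in 3' UTRs 71 bp.

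First introns were longer than later ones. The 7941 first introns had a median of 82 bp (quartiles 65 and 129 bp) and the 9042 later ones 71 bp (quartiles 60 and 97 bp). The sequence medians were 81.7 ± 1.80 bp and 70.6 ± 0.787 bp, and the difference of 11.1 ± 2.41 bp (SD) was above 0 on 7 of 7 sequences (exact two-sided sign-flip permutation test, p = 0.0156, adjusted p = 0.0156). By position, the median fell from 82 bp at the first to 73 bp at the second and 69 bp at the third intron, and lay between 67 and 68 bp from the fourth on. Within the 4620 genes that had 2 or more introns, the first exceeded the mean of the later ones by a median of 5.86 ± 1.41 bp (exact permutation p = 0.0156). The 11.1 bp between all first and all later introns is a difference of medians. It is a different measure, so the 2 sizes cannot be compared directly.

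**Figure D2:**
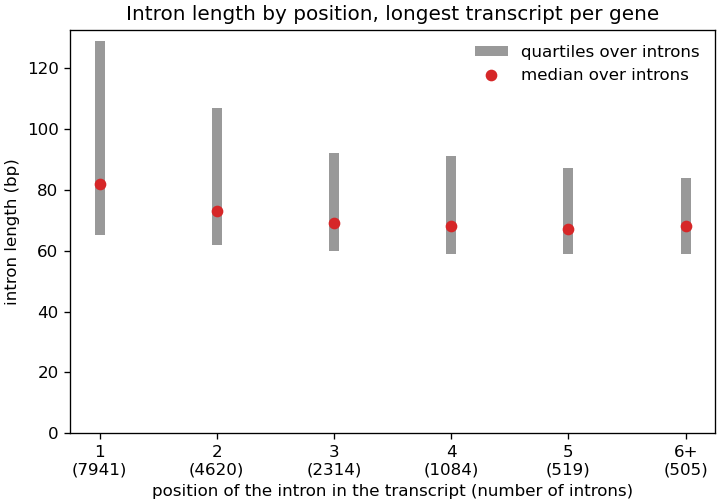
Intron length in bp by position of the intron in the longest transcript of each N. crassa gene, with the number of introns in brackets. Red points are medians and grey bars span the quartiles; the median is 82 bp at the first position and 67 to 73 bp at the others.

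The genes at the extremes of these measures were the following. NCU02793, on the plus strand of sequence 1 at 9117558 to 9151762, had both the longest span, 34205 bp, and the most transcripts, 5. Its longest transcript had 13 exons and a coding length of 32127 bp, a 5' UTR of 385 bp and a 3' UTR of 460 bp, and its span overlapped 0 other genes. NCU06011, on the plus strand of sequence 6 at 3092610 to 3097787, had the most exons, 17, and neither UTR. NCU16682, on the minus strand of sequence 3 at 3700332 to 3706039, held the longest intron. It is the second of that transcript, runs from 3702039 to 3703922 within the coding span and measures 1884 bp. The longest divergent gap, 321175 bp, separated NCU09667 and NCU16947 on sequence 5.

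Each sequence held a long interval with no annotated gene. The longest ran from 3819947 to 3972682 on sequence 1 (152736 bp), from 1154522 to 1366018 on sequence 2 (211497 bp) and from 813978 to 965450 on sequence 3 (151473 bp). On sequence 4 it ran from 874451 to 994037 (119587 bp), on sequence 5 from 897950 to 1219124 (321175 bp), on sequence 6 from 2769627 to 3080311 (310685 bp) and on sequence 7 from 2135114 to 2482903 (347790 bp). Of the 9723 gaps, 213 were longer than 10 kb, 24 were longer than 50 kb and 9 longer than 100 kb. Every gene of the annotation has a coding region, so these intervals can hold other kinds of genes.

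**Figure D3:**
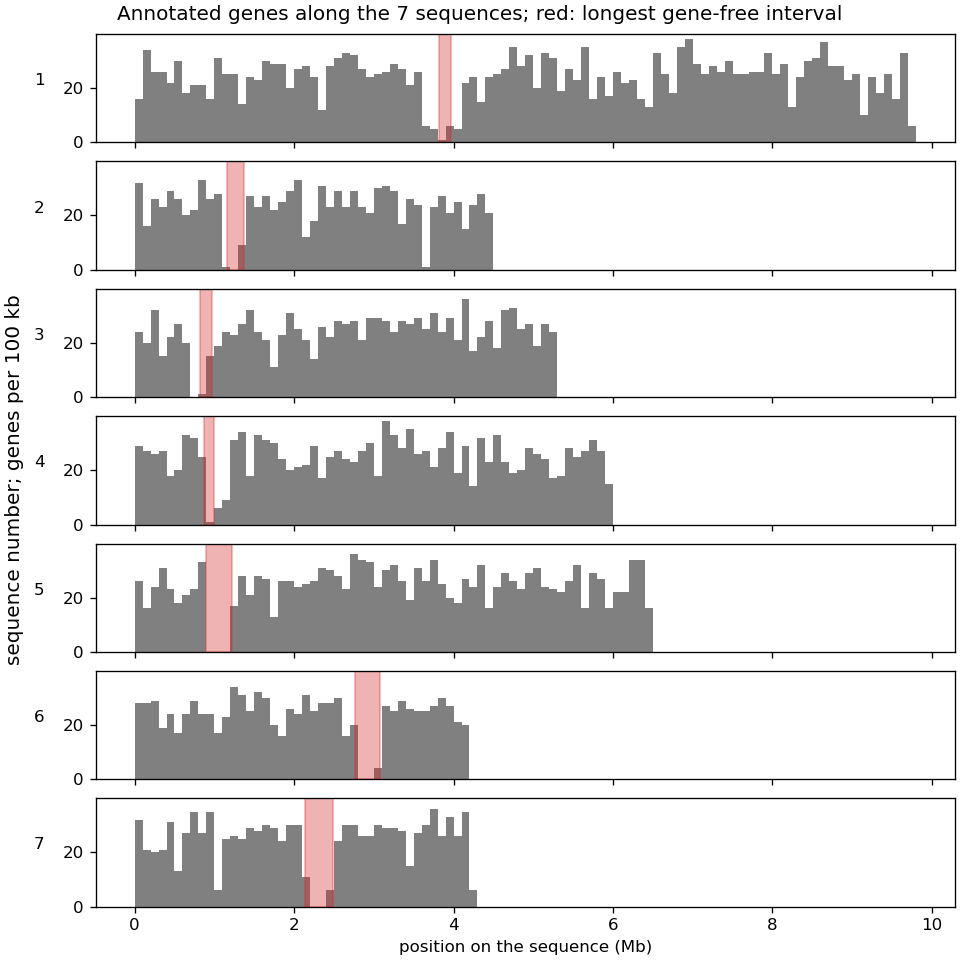
Number of annotated N. crassa genes per 100 kb (grey bars, by gene midpoint) along the 7 sequences, against position in Mb, with the longest gene-free interval of each sequence in red. The intervals are between 119587 and 347790 bp long, and there is 1 marked per sequence.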

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

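The test on pairs with annotated UTRs and that on 1 missing 5' UTR were chosen after the results were seen, and the coding-span tests, planned as alternatives, were read as tests of an explanation only then. The tests within genes and on pairs with neither 5' UTR were set before their results were seen. Of 8 quantities checked over the 7 sequences, 1 stood apart: the median intron length of sequence 3 was 77 bp, against 75 bp on all 6 others. Chance marks about 1 in 20 sets of continuous values, and 8 sets were checked. Here the values are whole numbers of which 6 are tied, so any single different value would stand apart.

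Convergent gaps were shorter than divergent gaps by 595 bp. UTRs missing from some gene models do not account for it, since among pairs with both facing UTRs annotated the difference was 543 ± 22.2 bp (SE, 7 of 7 sequences above 0). Overlong 3' UTRs do not account for the whole either, since between coding spans the difference was 608 ± 45.8 bp. A candidate explanation is that the stretch between facing starts holds promoters and that between facing ends does not. It was not tested, but tandem gaps, which hold 1 start, bear on it. The sequence medians averaged 831 bp for tandem, 776 bp for divergent and 181 bp for convergent pairs. Gaps with a start were thus longer than those without. Those with 2 starts were on average not longer than those with 1, but this order was not tested and varied. The divergent median was below the tandem one on sequences 1, 2, 3, 5 and 6 and above it on sequences 4 and 7. Between coding spans, tandem gaps lay between the other kinds in N. crassa, S. pombe and S. cerevisiae. In N. crassa they averaged 1466 ± 68.4 bp, close to the 1484 ± 55.9 bp of divergent pairs and above the 876 ± 82.1 bp of convergent pairs (SD). These values do not decide the question.

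First introns were longer than later ones. Introns within 5' UTRs do not alone account for it, since within coding spans the difference was 9.71 ± 0.918 bp (SE). Genes with few introns may contribute, but cannot alone be the whole cause, since within genes the first intron still exceeded the mean of the later ones by 5.86 ± 0.533 bp. The test within genes kept introns of 5' UTRs, and that within coding spans kept genes with few introns. Whether both sources together account for the difference was therefore not tested. No biological explanation was tested.

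Divergent gaps were longer where a 5' UTR was missing from the annotation. The median gap was 1411 bp for the 155 pairs with neither 5' UTR and 566 bp for the 1942 pairs with both, a mean difference over sequences of 835 ± 162 bp (SE). Between coding spans the difference was -42.1 ± 147 bp, which is consistent with the missing UTRs being the source of it, although the few pairs leave a wide margin. For the 585 pairs with 1 annotated 5' UTR, coding spans lay 299 ± 71.6 bp further apart than with both (6 of 7 sequences above 0), so there the missing UTR is not the whole cause, and why these genes lie further apart was not tested.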

How the results depend on the processing

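No paired analysis was possible between libraries, because their footprints were not analysed here; both planned tests compare values within each sequence. Of 31 alternatives over 5 results, 27 left the result on the same side of its test or within 1 SD of its value. These include the runs that left out 1 sequence, which could not fail their tests. Pairs with both facing UTRs, introns within genes and upstream windows from coding spans were added after seeing the data. The 4 exceptions all concern the share of gene starts with 1000 bp free of other genes, 42.7%. It was 63.6% with a window of 500 bp, 87.0% with 200 bp, 73.5% with same-strand neighbours alone and 70.9% from coding spans. The first 2 follow from the shorter window, and the next from counting fewer neighbours. The difference between divergent and convergent gaps passed its test under all 13 alternatives. It ranged from 190 bp (overlapping pairs left out) to 943 bp (means, which single long gaps can move), against 595 bp. Leaving out overlaps selects pairs by the gap itself and removes mostly convergent ones, so the difference must shrink. Leaving out each sequence in turn gave 577 to 608 bp, with an exact permutation p of 0.0313, the smallest that 6 sequences allow. Since all 7 sequences lay above 0, that p was fixed in advance, and these runs bear only on the size of the difference. The difference between first and later introns passed under all 9 alternatives, with values of 10.5 to 11.5 bp when each sequence was left out. There too all 7 sequences lay above 0, so passing was fixed in advance for the runs without a sequence. Restricting to genes with a CDS removed no gene and leaving out introns under 20 bp removed no intron, so these 2 say nothing of stability. The annotation has no sequencing depth, and no limit of depth applies to these values.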

Other observations

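The comparison of species and the test of reading frame were chosen after the data were seen; the test of the surroundings of the long intervals was set before its result was seen. In these annotations the 3 fungi of the design differed in the room between their genes. Between coding spans, divergent neighbours lay 1484 ± 55.9 bp apart in N. crassa (mean of sequence medians ± SD, n = 7), 1053 ± 86.3 bp in S. pombe (n = 3) and 521 ± 60.4 bp in S. cerevisiae (n = 15 chromosomes with at least 100 genes). Convergent neighbours lay 876 ± 82.1 bp, 400 ± 76.1 bp and 221 ± 26.8 bp apart, and tandem neighbours 1466 ± 68.4 bp, 780 ± 100 bp and 394 ± 27.1 bp. Each species is represented by 1 annotation, so the SDs describe the spread between chromosomes of that annotation, and a difference between species was not tested apart from the source of the annotation.

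Divergent gaps exceeded convergent ones on every chromosome counted, 7 of 7, 3 of 3 and 15 of 15, by 1.69 times in N. crassa, 2.63 times in S. pombe and 2.36 times in S. cerevisiae. Convergent coding spans under 150 bp apart made up 2.50% of convergent pairs in N. crassa, 12.05% in S. pombe and 28.7% in S. cerevisiae. The 3 annotations come from different sources, and a gene that one of them leaves out lengthens a gap there.

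The hypothesis that the longest gene-free interval of each sequence lies in gene-poor surroundings was tested on the 5 gaps on each side of it. Of these 70 gaps, 6 were longer than 10 kb, against a median of 1 and a highest of 8 in 10000 random orders of the gaps within each sequence (one-sided permutation p = 0.0041). Long gaps were thus more frequent beside the longest intervals than in most random orders. The count is summed over sequences and the orders shuffle single gaps. It therefore does not show how many of the intervals have gene-poor surroundings. Whether such stretches are centromeres, or repeats that the gene calls left out, was not tested without the genome sequence.

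The hypothesis that coding introns avoid lengths divisible by 3, which would keep the reading frame if the intron were retained, was not borne out. Such lengths made up 33.6% ± 0.390 (SE, n = 7 sequences) of coding introns, against 33.3% if the 3 remainders were equally frequent.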
